A study of Homo sapiens with 8 samples.

How the data were processed

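Gene expression was measured by RNA sequencing in cells of 1 primary acute myeloid leukaemia sample collected by leukapheresis. The cells were thawed, cultured in medium with conditioned medium, and treated in culture for 24 h with 100 nM tamibarotene or with an equal volume of the solvent DMSO, at no more than 0.1% DMSO. Each group had 4 libraries. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and libraries were prepared by NEB protocols. The labels call the 4 libraries of each group biological quadruplicates of the same sample. No p-value therefore covers a spread between donors. Groups were taken from the sample titles, which match the treatment label, because the free-text description named DMSO for all 8 samples.

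The deposited values are FPKM per gene (fragments per kilobase of transcript, relative to all mapped fragments), made by the authors with STAR and Cuffnorm on the hg19 genome, per the submitters' processing notes. The notes give no versions, and the gene annotation is not given in the sources used here. Each table held 26341 rows, of which 92 were ERCC spike-ins, synthetic RNAs added in known amounts. The spike-in rows summed to between 15782 and 16273 in the 8 libraries, whereas the genes summed to between 416785 and 621284. Values that close among spike-ins would result from scaling to the spike-ins, but such a step is not given in the sources used here. In each library 6997 genes shared the most common value, which lay between 0.0945 and 0.107 FPKM and was treated as a floor. FPKM values hold no read counts, so the depth is unknown and no counting interval was computed. A different scaling by the authors would shift all genes of a library together, and a gene whose estimate failed would appear at the floor.

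Before the data were examined, the test, the filter, the 22 gene lists, the rule for named genes and most alternatives were fixed. Rows that could tell of the donor, such as sex-linked, copy-variable and receptor variable-segment genes, were left out (128 rows), which left 26121 genes. Genes with a mean of at least 1 FPKM over the 8 libraries were tested, 11448 in all. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and no covariate. In this main fit limma's prior degrees of freedom were infinite, so each gene's variance was the trend value shared at its expression level. Its SE and p-values therefore do not reflect the gene's own spread between cultures. The test was two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes of low expression. Gene lists with at least 3 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01, adjusted over the lists. At that setting its p-values rest on the spread between genes, not between cultures. Camera with an estimated correlation and fry were run as alternatives.

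Genes were named by a rule. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and up to 4 called members of each list by size of change. Where no member of a list was called, it took the 2 members of highest expression. RARA, RARB, RARG, RXRA, RXRB and RXRG were always included. In 1 case a gene taken by the rule was not named, because its expression can tell of a donor's genotype, and some others it took are not reported here. Genes were identified by symbol only, and no coordinates were used because the reference at hand was of another build.

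The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, and 4 other scalings (quantile, median log ratio, a fixed library sum as TPM, and ERCC). Further ones were the replicate number as a block, each library left out in turn, no variance trend, a robust fit, library weights, and the other list tests. An alternative with raw counts was not run because the values are FPKM. After the data were seen, 3 more were added: leaving out genes whose values ranged over 10-fold within a group, no moderation of the variance, and median scaling together with an estimated correlation.

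The procedure was tested on simulated data with the observed gene means and gene spreads and with the library offsets centred within each group, for the comparison of tamibarotene with DMSO over 11448 genes. With the deposited scale, it recovered 18% of 50 genes changed by 0.5 on the log2 scale, and 100% at each of the log2 changes 1, 2 and 4. There, 45 of 204 calls were false, a larger share than the threshold allows. The centring leaves out any difference of library offsets between the groups, so its effect on the calls was not simulated. With median scaling it recovered 92% at 0.5 and 100% at the larger changes, and 7 of 203 calls were false.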

Results

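Tamibarotene is a synthetic retinoid that activates the retinoic acid receptor RARA. The data compare the transcriptome of primary acute myeloid leukaemia cells after 24 h with 100 nM tamibarotene with that of the same cells in DMSO. There were 4 libraries per group, all from cultures of 1 sample, and the values are FPKM. The depth is unknown, because the tables hold no counts. Between 10817 and 11571 genes per library reached 1 FPKM. The FPKM of all genes summed to 526300 ± 84350 (SD, n = 4) with DMSO and 528900 ± 40370 (SD, n = 4) with tamibarotene (two-sided exact permutation test, p = 0.971; the smallest p it allows is 0.0286). Correlations of log2 values across genes, which are not independent replicates, were 0.979 to 0.988 within groups and 0.955 to 0.970 between groups.

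Tamibarotene raised the expression of genes including several of the retinoic acid response and lowered several myeloid effector genes. DHRS3, a retinaldehyde reductase, rose from 0.621 ± 0.0565 to 97.3 ± 10.4 FPKM (SD, n = 4 each), a log2 fold change of 5.92 ± 0.18 (SE, from the variance trend). THBD, the thrombin cofactor thrombomodulin, rose by 4.62, from 4.63 ± 1.30 to 134.9 ± 11.05 FPKM. The transcriptional repressor HIC1 rose by 4.58 and the transglutaminase TGM2 by 4.29. Further large rises were those of the actin-associated PALLD (3.94), the fructose transporter SLC2A5 (3.89), the G protein subunit GNG2 (3.89), the secreted glycoprotein CHI3L1 (3.70) and the transcription factor MLXIPL (3.25). The small nucleolar RNA SNORA70 was also among the 10 largest rises (3.41), but its DMSO values ranged from 0.0906 to 28.6 FPKM and its call was lost in 3 alternatives.

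The largest falls were in the calgranulins, calcium-binding proteins of neutrophils and monocytes. S100A8 went from 494.4 ± 42.0 to 67.2 ± 4.21 FPKM (SD, n = 4 each), S100A9 from 952.9 ± 119.8 to 136.2 ± 10.6 FPKM and S100A12 from 10.8 ± 3.14 to 0.696 ± 0.267 FPKM, with log2 fold changes of -2.86, -2.79 and -2.78. The myeloid lectin CLEC5A (-2.53), the proteoglycan VCAN (-2.32), the potassium channel KCNN4 (-2.27), the cystatin CST7 (-2.26), the chaperone CLU (-2.05), the granule protease CTSG (-1.93) and the AP-1 subunit FOS (-1.90) followed. These 20 genes were selected among those whose groups did not overlap. In limma with Benjamini-Hochberg adjustment and median scaling, the adjusted p was 0.0258 for SNORA70 and at most 8.89e-06 (FOS) for the other 19.

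**Figure D1:**
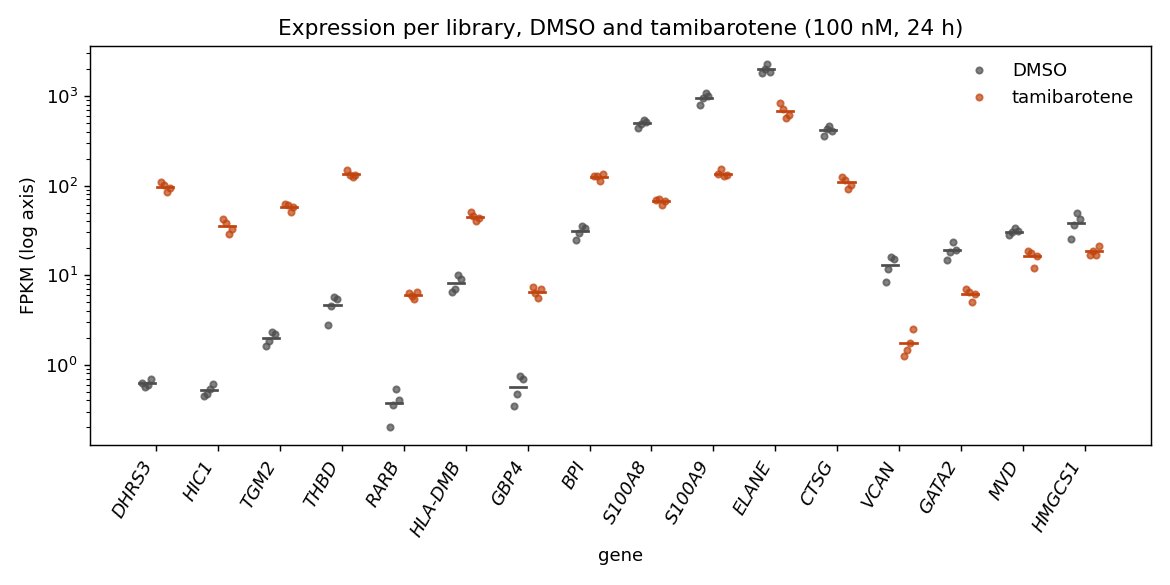
FPKM on a log axis for 16 genes in each library; points are the 4 DMSO and 4 tamibarotene libraries and bars the group means. DHRS3 had means of 0.621 and 97.3 FPKM, and S100A9 had means of 952.9 and 136.2 FPKM.

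In total, 955 genes rose and 396 fell of 11448 tested (limma, Benjamini-Hochberg adjusted), and 273 of these changed at least 2-fold, 198 upward and 75 downward. The 2-fold count was 429 with a pseudocount of 0.1 and 118 with a pseudocount of 5. With no moderation of the variance, 368 genes rose and 127 fell. In the simulation on the deposited scale, 45 of 204 calls were false, a larger share than the threshold allows. That simulation changed only 50 genes at each size of change, far fewer than were called in the data, so its false share does not carry over. The counts of 955 and 396 may still hold more false calls than the adjustment states, by a share that was not estimated. Of the called genes, 65 ranged over 10-fold within a group; without such genes 232 changed at least 2-fold. The share of higher genes among the calls was 70.7% on the deposited scale. After scaling each library to the same median it was 48.9%, with 2710 higher and 2828 lower, and that scaling moved the median log2 fold change of all genes from 0.11 to 0.00. Of the calls on the deposited scale, 1278 had the same direction after median scaling and 0 the opposite one, and 226 genes then changed at least 2-fold, 145 upward and 81 downward. Groups did not overlap for 1554 genes, or 13.6% of those tested, against 2.86% by chance.

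The counts over all sizes of change depended on single libraries, while 264 to 309 genes changed at least 2-fold with any library left out. The number of higher genes was 598 without DMSO replicate 2, 2202 without DMSO replicate 3, 634 without tamibarotene replicate 1 and 575 without tamibarotene replicate 4. The number of lower genes was 1107 without DMSO replicate 1. Among the 48 spike-ins with a mean of at least 1 FPKM, 0 were called higher and 1 lower (ERCC-00077, -0.75), with a median log2 fold change of -0.04. Scaling to the spike-ins, if it was done, would itself leave few such differences.

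Genes of the retinoic acid response rose as a group. Of the 14 tested, 9 rose and 2 fell, and adjusted over the list alone 9 rose and 3 fell. Besides DHRS3, HIC1 and TGM2, the phospholipase RARRES3 rose by 2.86, from 2.35 ± 0.586 to 23.1 ± 3.33 FPKM (SD, n = 4 each), and the receptor gene RARB by 2.36. The median log2 fold change of the list was 1.28. Camera gave an adjusted p of 4.3e-41 in limma, an adjusted p of 0.0462 with an estimated correlation, and an adjusted p of 0.0656 with an estimated correlation after median scaling. The members that fell were the retinol dehydrogenase DHRS9 (-1.46, chosen after its value was seen) and RARG (-0.45).

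Among the drug's receptors and their partners, RARB rose from 0.374 ± 0.139 to 6.03 ± 0.522 FPKM (SD, n = 4 each), whereas the main target RARA was 16.7 ± 3.74 and 17.4 ± 2.12 FPKM. The RARA log2 fold change of 0.07 did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.843) and was -0.04 with median scaling. RARG and RXRA fell, by limma with Benjamini-Hochberg adjusted p of 0.0442 and 0.0473 and log2 fold changes of -0.45 and -0.49, calls that were lost for RARG and for RXRA in 13 alternatives each. RXRB was at 0.15 and did not pass, and RXRG was at the floor in all 8 libraries. Of the 16 tested retinoid receptors and cofactors, 3 rose and 2 fell, and adjusted over the list alone 3 rose and 2 fell. The coregulators NRIP1 (1.68) and NCOA3 (1.15) were the other rises. The list was called higher by camera in limma (adjusted p = 0.0261), with an adjusted p of 0.925 with an estimated correlation and 0.347 after median scaling.

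Granulocyte differentiation genes moved in both directions. Of 20 tested, 5 rose and 8 fell (adjusted over the list alone, 6 and 8). The antibacterial protein BPI rose by 1.99, from 30.9 ± 4.74 to 125.1 ± 8.77 FPKM (SD, n = 4 each), while the 3 calgranulins fell. The list's median was 0.11, its mean -0.24 and its camera direction lower (limma adjusted p = 0.000229; adjusted p = 0.893 with an estimated correlation). After median scaling it did not pass (adjusted p = 0.596).

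Primary granule genes encode the proteases and antimicrobial proteins of promyelocytes. They fell as a group in camera at its preset correlation and in fry, but not in camera with an estimated correlation. Of 14 tested, 0 rose and 6 fell (adjusted over the list alone, 1 and 8). The neutrophil elastase gene ELANE fell by 1.54 on the log2 scale, from 1981 ± 212.9 to 686.5 ± 124.2 FPKM (SD, n = 4 each). BPI, whose protein is also found in these granules, was a member of the granulocyte list and is not counted here. CTSG, CST7 and the serpin SERPINB10 (-0.60) fell as well, the last with its call lost in 8 alternatives. Camera in limma gave an adjusted p of 1.46e-08 on the deposited scale and 0.000566 with median scaling. The call was lost in camera with an estimated correlation (adjusted p = 0.525, and 0.234 after median scaling) and kept in fry (adjusted p = 0.0267).

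Monocyte and macrophage genes were split. Of 21 tested, 7 rose and 6 fell (adjusted over the list alone, 9 and 7), with LYZ counted among the rises. VCAN and the haemoglobin scavenger receptor CD163 (-1.28) were among the falls. The lysozyme gene LYZ was listed near 0.1 FPKM in all 4 DMSO libraries and in tamibarotene replicate 1, and at 14150 to 16130 FPKM in the other 3 tamibarotene libraries, so its fold change is not interpreted. The list's camera direction was higher (limma adjusted p = 0.0162; adjusted p = 0.925 with an estimated correlation), with a median of -0.002 and a mean of 0.40 that rests on LYZ. It turned lower without the genes ranging over 10-fold within a group, LYZ among them (adjusted p = 0.0162), and after median scaling (adjusted p = 0.596).

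Part of the antigen presentation and interferon genes rose. Of 11 MHC class II presentation genes, 8 rose and 0 fell (adjusted over the list alone, 9 and 0). The peptide-loading gene HLA-DMB rose by 2.34, from 8.15 ± 1.69 to 45.03 ± 4.35 FPKM (SD, n = 4 each), HLA-DMA by 1.06, HLA-DPA1 by 0.95 and HLA-DRA by 0.76. The camera test in limma had adjusted p = 1.31e-07, and adjusted p = 0.525 with an estimated correlation. With an estimated correlation after median scaling it was 0.0656, and fry called the list higher (adjusted p = 0.0081). Of 32 interferon-stimulated genes, 18 rose and 0 fell (adjusted over the list alone, 24 and 0). They included the GTPase GBP4 (2.27), the antiviral IFITM3 (0.90), DDX60 (0.89) and IFIT3 (0.82). The list passed camera in limma with adjusted p = 1.26e-07, and adjusted p = 0.849 with an estimated correlation. With an estimated correlation after median scaling it was 0.108, and fry called the list higher (adjusted p = 0.0267). Of 17 MHC class I presentation genes, 5 rose and 0 fell (adjusted over the list alone, 8 and 0), among them HLA-F (0.76), the proteasome activator PSME2 (0.55) and the regulator NLRC5 (0.52), whose calls were lost in 5 and 10 alternatives. For this list limma camera had adjusted p = 0.0162, and adjusted p = 0.925 with an estimated correlation. Fry did not call it (adjusted p = 0.0834).

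Sterol biosynthesis genes fell together. Of 19 tested, 0 rose and 14 fell (adjusted over the list alone, 0 and 17). HMGCS1, which makes the precursor of mevalonate, fell by 0.99 on the log2 scale, from 38.3 ± 10.2 to 18.4 ± 2.07 FPKM (SD, n = 4 each), a call lost with no moderation of the variance (limma, Benjamini-Hochberg adjusted p = 0.0697). MVD and LSS, later enzymes of the pathway, had log2 fold changes of -0.90 and -0.88. The list's median was -0.67. Camera in limma gave adjusted p = 2.56e-11, an adjusted p of 0.525 with an estimated correlation, and an adjusted p of 0.0216 with an estimated correlation after median scaling. Of 12 LXR and PPAR target genes, the apolipoprotein gene APOC1 rose (1.48) and the desaturase SCD fell (-0.67), as also when adjusted over the list alone (1 and 1). With median scaling 2 rose and 6 fell, and the call of SCD was lost in 2 alternatives. That list did not pass (limma camera adjusted p = 0.797), with a median of -0.05 and a mean of 0.06.

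A few cell cycle genes fell. Of 35 tested, 0 rose and 4 fell (adjusted over the list alone, 0 and 4), namely TK1 (-0.57), E2F1 (-0.52), CDC20 (-0.52) and PLK1 (-0.51). The calls of E2F1, CDC20 and PLK1 were each lost in 10 alternatives, and that of TK1 in 8. The median was -0.25, and with median scaling 30 fell. Camera in limma gave adjusted p = 1.27e-05, an adjusted p of 0.925 with an estimated correlation, and an adjusted p of 0.0216 with an estimated correlation after median scaling. Ribosome biogenesis and MYC target genes had 0 of 34 called in limma with Benjamini-Hochberg adjustment, and 0 adjusted over the list alone. With median scaling 18 fell and the camera adjusted p went from 0.0764 to 0.00119. Over all genes tested on the deposited scale, the median log2 fold change was 0.18 at a mean log2 FPKM of up to 2. It was -0.06 above 8, and the list test did not account for this trend with expression. The nucleolar NCL (0.02, and -0.10 with median scaling) and NPM1 (-0.05, and 0.04 with quantile normalization) did not pass on the deposited scale, and NPM1 was called lower with median scaling (-0.17, adjusted p = 0.0131).

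Regulators of myeloid identity moved in both directions. Of 26 myeloid transcription factors, 5 rose and 7 fell (adjusted over the list alone, 5 and 7), against 6 and 12 with median scaling, with RUNX2 (1.74) up and FOS and EGR1 (-1.83) down. The list had a median of 0.01, a mean of -0.05 and a lower direction that did not pass (limma camera adjusted p = 0.117). Of 17 stem and progenitor genes, 5 rose and 3 fell (adjusted over the list alone, 5 and 4). SOX4 (0.95) and the receptor gene KIT (0.84) rose, and the transcription factors GATA2 (-1.46) and ERG (-0.76) fell, with the call of ERG lost in 2 alternatives. Camera in limma gave that list an adjusted p of 0.863 and a lower direction, against a median of 0.16 and a mean of 0.09, and a higher direction with median scaling.

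Of 24 p53 target genes, 5 rose and 0 fell (also adjusted over the list alone), against 11 and 4 with median scaling. The rises included TP53INP1 (1.00), ZMAT3 (0.90), TP53I3 (0.84) and GADD45A (0.82). The list did not pass (limma camera adjusted p = 0.146). Of 14 BCL2 family genes, the proapoptotic BMF rose (0.77) and the antiapoptotic BCL2 fell (-0.69), as when adjusted over the list alone (1 and 1; camera adjusted p = 0.973), against 4 and 3 with median scaling. Of 18 NF-kB and inflammatory genes, 2 rose and 4 fell (adjusted over the list alone, 3 and 4). ICAM1 (1.00) and IL1B (0.67) rose, whereas the interleukin-1 antagonist IL1RN (-1.52) and the urokinase receptor PLAUR (-0.63) fell. That list had a median of 0.11, a mean of -0.01 and a lower direction (limma camera adjusted p = 0.321). Of 16 stress response genes, DDIT4 (0.72) and ASNS (0.68) rose and 0 fell (adjusted over the list alone, 2 and 0), against 3 and 8 with median scaling. The calls were lost in 2 alternatives for DDIT4, 3 for ASNS and 3 for PLAUR. The stress list had a median of -0.06, a mean of 0.05 and a lower direction (limma camera adjusted p = 0.724).

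Markers of other cell types did not pass the test over all genes in limma on the deposited scale. With median scaling, ACTA2 (0.35, adjusted p = 0.00099), IL7R (0.23, 0.0229), GP1BA (0.29, 0.0253) and BANK1 (0.28, 0.0363) were called higher in limma. Of the B and plasma cell markers, 4 were tested (camera adjusted p = 0.646), with BANK1 at 0.37 and CD79B at 0.06, the latter -0.04 with median scaling. Of the T and NK cell markers, 2 were tested: NKG7 was at 40.5 ± 4.21 and 40.7 ± 4.29 FPKM (SD, n = 4 each), with a log2 fold change of 0.01 (-0.11 with median scaling), and IL7R was at 0.33. The platelet receptor gene GP1BA (0.35) was the 1 tested erythroid and megakaryocyte marker, and the stromal markers ACTA2 (0.46) and TAGLN (0.15, and -0.06 with quantile normalization) were the 2 tested of that list. Adjusted over the list alone, 0 B and plasma cell, 0 T and NK cell, 1 erythroid and megakaryocyte, and 1 stromal marker rose.

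**Figure D2:**
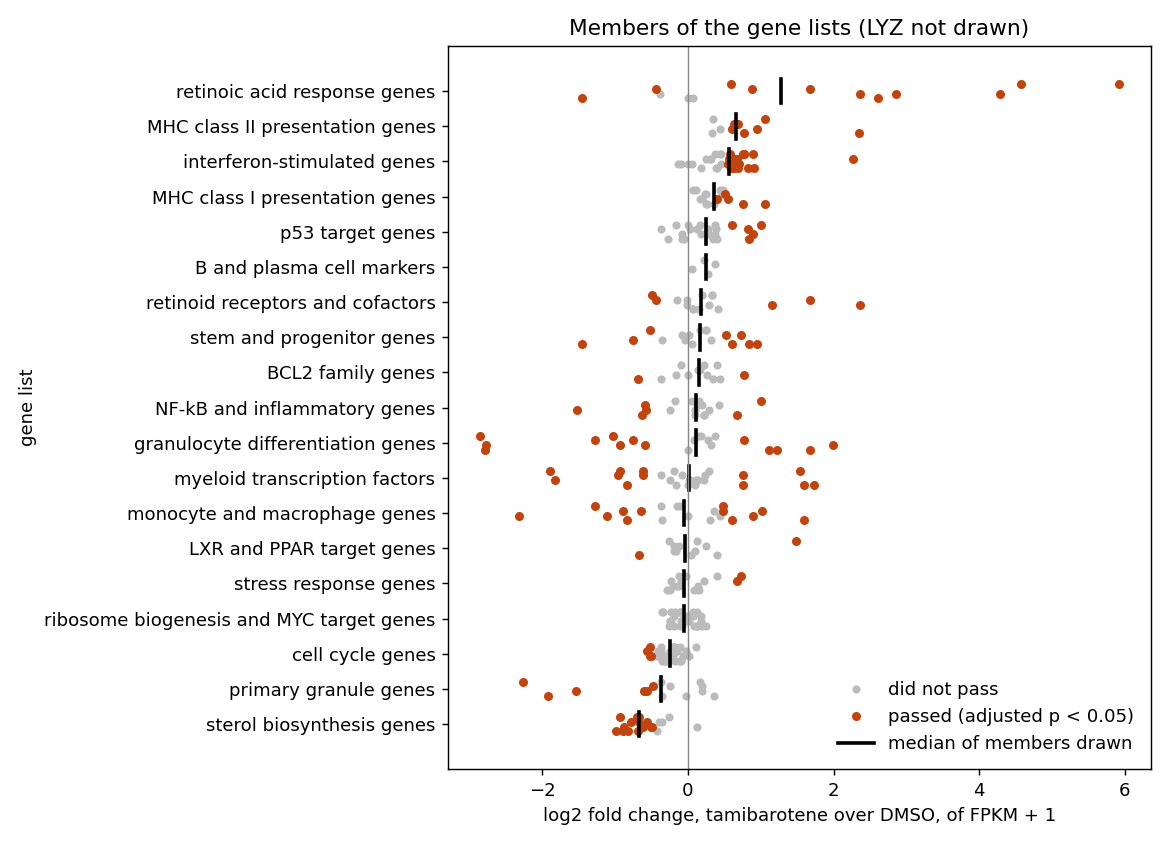
Log2 fold change of FPKM + 1, tamibarotene over DMSO, for each tested member of the 19 lists with at least 3 tested members; coloured points passed the test, grey points did not, and black bars are medians. LYZ is not drawn, and the list medians run from -0.67 for sterol biosynthesis to 1.28 for the retinoic acid response; directions of the monocyte and macrophage list and the stem and progenitor list in camera flip with median scaling.

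In all, camera called 6 lists higher and 4 lower of the 19 tested (limma, Benjamini-Hochberg adjusted). With an estimated correlation 1 call held, that of the retinoic acid response. With median scaling and an estimated correlation 2 held, those of sterol biosynthesis and the cell cycle. On the deposited scale the estimated correlations ran from 0.45 (B and plasma cell markers) to 0.89 (cell cycle). After median scaling they ran from -0.04 (p53 targets) to 0.38 (MHC class I). The library offsets, which median scaling removes, thus entered the estimates on the deposited scale. A call lost there does not by itself show that a list's change was absent. With median scaling, the numbers of members called higher and lower were 7 and 8 for granulocyte differentiation, 9 and 10 for monocytes and macrophages, 1 and 9 for primary granules, 7 and 6 for stem and progenitor genes, and 3 and 6 for NF-kB. They were 25 and 1 for interferon, 10 and 0 for MHC class I, 11 and 0 for MHC class II, 0 and 18 for sterol biosynthesis, 6 and 3 for retinoid receptors and cofactors, and 9 and 3 for the retinoic acid response. Of the 35 ways to split the 8 libraries into 4 and 4, 17 gave the cell cycle list an adjusted p as small as the real split, 13 MHC class I, 11 the interferon and 11 the sterol list, 7 the monocyte and macrophage list, and 6 each the granulocyte and MHC class II lists. With median scaling the counts were 1 for the cell cycle, sterol and MHC class II lists, 2 for interferon and 9 for MHC class I. For the retinoic acid response and primary granule lists, the real split alone gave as small a value on both scales.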

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

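Among the tests below, the counts of splits were chosen before their results were seen, those with median scaling after the ones on the deposited scale; the other tests were chosen after the pattern they address was seen. Values were checked in 176 groups of 4, for named genes, SRGN and 5 library measures, and chance sets apart a value in about 1 in 20 such groups; 8 were set apart.

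LYZ, and the granule proteoglycan gene SRGN, stood at the floor in some libraries. LYZ was listed at 0.103 FPKM in tamibarotene replicate 1, against 14150 to 16130 FPKM in the other tamibarotene libraries (gap over range 0.877), and SRGN at 0.114 against 15430 to 17150 FPKM (0.900). All 10 values of the 2 genes off the floor exceeded every other gene of their library, as estimates that fail for loci with too many fragments may require. A mislabelled or untreated replicate 1 is argued against by its 9 called-higher retinoic acid response genes, whose median log2 difference to the DMSO mean was 2.72, against 2.51 to 2.65 in the other libraries. A response of LYZ to tamibarotene cannot be told apart from failed estimates, because a value at the floor can be a failed estimate in either group.

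The 10 most abundant genes took 7.05% of the FPKM in tamibarotene replicate 1 and 11.4% to 11.9% in the other 3 (gap over range 0.901). LYZ and SRGN, at the floor in replicate 1, were the most abundant genes of the other 3, so this gap is not separate from theirs. Further single values were set apart from the other 3 of their group. With DMSO, APOC1 was 8.90 FPKM in replicate 3 against 5.56 to 5.81 (0.923), GADD45A was 12.8 in replicate 3 against 10.7 to 11.04 (0.837), and GP1BA was 0.746 in replicate 1 against 1.02 to 1.06 (0.861). With tamibarotene, CST7 was 2.45 in replicate 2 against 1.82 to 1.92 (0.835), and SERPINB10 was 17.9 in replicate 4 against 18.3 to 18.4 (0.834).

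Of 122 list genes below the expression filter, 5 were over 2 times higher in every tamibarotene library than in any DMSO library, and 1, MRC1, was lower in the same way. The 5 means with tamibarotene were 0.285 FPKM for CYP26A1 and 0.299 FPKM for CYP26B1, both retinoic acid hydroxylases, 1.13 FPKM for HLA-DOA, 1.13 FPKM for IFIT2 and 0.528 FPKM for ORM1. With DMSO they were 0.0981, 0.108, 0.280, 0.415 and 0.124 FPKM; those of both CYP26 genes were close to the floor.

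More genes were called higher (955) than lower (396). Without DMSO replicate 1, whose median offset of -0.47 was the lowest, the share of higher genes was 45.5%, but by a rise of the lower genes to 1107, with 925 still higher. An offset of that library shared by all genes therefore stays open as the source of the excess. Without DMSO replicate 3, with the highest offset, 0.25, it was 86.5%. More RNA per spike-in after tamibarotene cannot be told apart from chance offsets, with a mean difference of 0.12 and an exact permutation p of 0.6.

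S100A8, S100A9, S100A12 and VCAN fell by 2.32 to 2.86 on the log2 scale. Fewer monocytes in the culture are argued against by the other 19 monocyte and macrophage genes, LYZ left out, with a median of -0.002 and an SD of 0.772. For fewer mature granulocytes, the other 17 tested granulocyte differentiation genes had a median of 0.179 and an SD of 0.944, so as a set they did not fall. They cannot decide the question, because list members such as FCGR3B, LTF and LCN2 were near the floor in both groups and not tested. A residue of the scaling at their expression level is argued against by the 400 genes nearest in mean FPKM, 100 for each, with a median of 0.0473 and an SD of 0.359. A fall of these transcripts within the cells stays open as a hypothesis.

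Other splits of the 8 libraries into 4 and 4 were tested, 35 in all. For the number of genes called, 1 split, the real one with 1351, was as large, and the highest other gave 3. For 2-fold changes it was 1 split, with 273 against 3. For the retinoic acid response list it was 1 split, with adjusted p = 4.3e-41 against 2.62e-09. For these 3 results the real split alone was as extreme, the fewest that 35 splits allow. Every other split mixes treated and untreated libraries, which puts the treatment effect into the spread within its groups. The split tests were also not adjusted for their number, so they do not by themselves exclude chance. Nor was chance excluded for the number of lists called, since 4 splits gave at least the real 10 and the highest other gave 11. By list, 1 split was as small for the primary granule list (1.46e-08 against 3.3e-07) and for the retinoid receptors and cofactors (0.0261 against 0.138). For the other called lists chance was not excluded: 6 splits for granulocyte differentiation, 7 for monocytes and macrophages, 17 for the cell cycle, 11 for interferon, 13 for MHC class I, 6 for MHC class II and 11 for sterol biosynthesis. The real adjusted p and the smallest other were 0.000229 and 5.45e-08, 0.0162 and 5e-04, 1.27e-05 and 1.27e-13, 1.26e-07 and 6.79e-13, 0.0162 and 1.01e-07, 1.31e-07 and 7.99e-10, and 2.56e-11 and 5.86e-20, in that order.

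With median scaling, which removes the library offsets, the real split alone was as small for 5 lists, with the same limits. These were the retinoic acid response (0.00041 against 0.0375), primary granules (0.000566 against 0.00362), the cell cycle (4.01e-13 against 8.03e-11), MHC class II (2.92e-07 against 2.42e-06) and sterol biosynthesis (1.58e-11 against 3.59e-09). More splits were as small for interferon (2 splits, 6.54e-08 against 1.45e-09) and MHC class I (9, 0.000927 against 7.73e-12), so chance was not excluded. The same held for granulocyte differentiation (14, 0.596 against 0.0856), monocytes and macrophages (9, 0.596 against 0.328), and retinoid receptors and cofactors (3, 0.347 against 0.302).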

How the results depend on the processing

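Most alternatives were fixed before the data were examined; 3 were chosen after (median scaling with an estimated correlation, no moderation, and leaving out genes with over 10-fold range within a group). Of 395 list tests compared, 336 kept their direction and side of the threshold, 34 were no longer past it, 6 came past it and 19 reversed; of 1809 gene values the numbers were 1659, 106, 21 and 23. The unknown depth left no counting error to set beside these values. Genes with a mean under 1 FPKM over the libraries used were tested only with no filter. Some genes near the floor in most libraries, such as SNORA18 and MIR4517, passed the filter and were called.

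Genes higher and lower with tamibarotene numbered 955 and 396. They were 3704 and 1697 with TPM, 2505 and 2651 with quantile normalization, 2710 and 2828 with median scaling, 3605 and 2301 with library weights (whose fit stopped before convergence), 528 and 245 with no trend, and 368 and 127 with no moderation. With a mean FPKM of at least 5 they were 472 and 256, where fewer genes were tested. With each library left out in turn, higher genes ranged from 575 to 2202 and lower genes from 264 to 1107. Genes changed at least 2-fold were 429 with a pseudocount of 0.1 and 118 with 5, which sets how far low genes move, and 264 to 309 over the libraries left out. For the other changes the cause was not tested.

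With the replicate number as a block, 475 genes were higher and 204 lower. Same-numbered libraries correlated at 0.211, 0.0042, 0.0184 and 0.103 in their deviations from the group means, and 1 of 4 DMSO libraries correlated best with its own number, so the numbers were not taken to pair the cultures.

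Lists higher were 1 with estimated correlation, 3 with fry and 0 with median scaling and estimated correlation; lists lower were 0, 2 and 2, and 8 with no filter on low values. Fry called the retinoic acid response, interferon and MHC class II lists higher, and the primary granule and sterol lists lower. The camera adjusted p of the retinoic acid response list went from 4.3e-41 to 0.0656 with median scaling and estimated correlation. The cause was not tested.

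The monocyte and macrophage list turned lower with no filter (adjusted p = 0.00104), quantile normalization (0.717), median scaling (0.596), TPM (0.283), library weights (0.383), without genes of over 10-fold range (0.0162), and with median scaling and estimated correlation (0.659). The stem and progenitor list turned higher with quantile normalization (0.626), median scaling (0.873), TPM (0.941), library weights (0.963), fry (0.769), and median scaling with estimated correlation (0.869). The LXR and PPAR list (0.769) and the stress response list (0.769) turned higher with fry, and the BCL2 family list lower with no filter (0.79) and in 3 of the fits without a library (adjusted p from 0.917 to 0.993 over all 8).

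None of the reversed genes passed on the deposited scale or in the fits that reversed them. With quantile normalization CD79B was -0.156, NKG7 -0.0382, NPM1 0.0449, RARA -0.0302 and TAGLN -0.0575; with median scaling CD79B was -0.0373, NCL -0.103, NKG7 -0.109 and RARA -0.0397. With TPM NCL was -0.0011 and NKG7 -0.0097; with library weights CD79B was -0.0565, NCL -0.0149 and RARA -0.0336. Over the libraries left out NCL ranged from -0.112 to 0.104, NKG7 from -0.0463 to 0.0839, RARA from -0.0592 to 0.187 and NPM1 from -0.190 to 0.0402. The cause was not tested.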

Other observations

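Further gene groups were described after the results were seen, from 8 lists written then. Integrin genes, which encode adhesion receptors, included 4 rises among 11 tested: ITGA6 (3.19), ITGAE (1.80), ITGB7 (1.63) and ITGAX (1.22). With median scaling 7 rose and 2 fell. As a list they were higher (limma camera adjusted p = 9.28e-07, and 0.0024 with median scaling), with an adjusted p of 0.592 with an estimated correlation. Of 48 lysosomal genes, 9 rose and 1 fell (14 and 13 with median scaling), and the list did not pass (limma camera adjusted p = 0.445). Of 18 cytosolic tRNA synthetase genes, 1 rose and 0 fell (4 and 3 with median scaling), and the list did not pass (adjusted p = 0.72).

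On the deposited scale, few genes of basic metabolism were called. Oxidative phosphorylation genes had a median log2 fold change of -0.06 over 76 genes, cytosolic ribosomal protein genes -0.02 over 80, proteasome genes -0.05 over 38 and glycolysis genes -0.16 over 22. In limma's camera their adjusted p were 0.014, 0.0295, 0.0403 and 0.0397. No call held with an estimated correlation, where the adjusted p was 0.924 for each of the 4. With median scaling 38 oxidative phosphorylation, 20 ribosomal protein, 23 proteasome and 15 glycolysis genes were called lower. Limma's camera adjusted p were then 0.000195, 0.00209, 0.000208 and 0.00209. Over all genes tested on the deposited scale, fold changes were lower at higher expression. Their median was 0.18 at a mean log2 FPKM of up to 2 and -0.06 above 8. The lists were not compared with genes of like expression, so a fall of their own was not told apart from this trend.

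FOS and EGR1 fell, and a hypothesis is that immediate early genes, which respond to stimulation within minutes, were lower together. The list of 15 had 5 falls and 0 rises (10 and 1 with median scaling), the others being EGR3 (-1.21), JUNB (-0.96) and ZFP36 (-0.65). Without FOS and EGR1, the other 13 may be lower (limma camera adjusted p = 0.00304, median -0.19), but the adjusted p was 0.728 with an estimated correlation, which leaves the hypothesis open. The test was chosen after FOS, EGR1 and JUNB had been seen.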
